A study of Homo sapiens with 10 samples.

How the data were processed

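Total RNA from SKGT4 cells, an established human oesophageal adenocarcinoma line, was measured on 10 Affymetrix Human Genome U133 A arrays, per the file headers for the chip type and per the labels for the samples. Resting cells formed the 0 min group, and cells kept at pH 6.5 for 30, 120, 180 or 240 min formed the other 4 groups, with 2 arrays in each of the 5 groups. Each deposited value was a linear probe set intensity, and the deposited table held no detection calls. The 2%-trimmed mean was 100 on every array, which was read from the values as a common scaling. The software that made the signals, its version and any other step before deposit were not given in the sources used here. The experiment sheets named only the chip type. All 10 columns of the table were used, with 0 columns left out.

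The deposited scaling was kept, since the trimmed means were equal. An offset of 7.7 signal units, the 20th percentile of all values, was added before log2, so that fold changes of dim genes are understated on this scale. Of the 22283 probe sets, 68 control probe sets were left out, and 14963 that exceeded 25.3 units, the 40th percentile of all values, on at least 2 arrays were kept. The platform annotation gave 1 gene symbol to 19065 probe sets, several to 1043 and none to 2107, leaving out the controls. Entrez identifiers matched 19059 of the single symbols to the reference, and 0 symbols needed an update. No gene was named from a probe set with several symbols. The kept probe sets with 1 symbol numbered 13192 and covered 8913 genes, each represented by the probe set with the highest mean. No genome coordinates were used.

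All 10 arrays were fitted together with limma, by lmFit with 1 mean per group and eBayes with an intensity trend, so that all groups shared 1 estimate of the spread. The fit had 5 residual degrees of freedom per probe set and 7.95 prior degrees of freedom, and the median standard error of a log2 change was 0.205. All adjusted p-values of genes are from limma, two-sided, with Benjamini-Hochberg adjustment over all kept probe sets within each of 7 comparisons, at a threshold of 0.05. The comparisons set each low pH group against 0 min and each later low pH group against the group before it. A moderated F test covered the 4 low pH groups against 0 min.

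Gene lists, 28 in number, were written from general knowledge and tested at each low pH time against 0 min with limma's camera at its preset correlation of 0.01, on 1 probe set per gene and lists of at least 5 measured genes, with adjustment over the lists within each time. Some genes belong to more than 1 list. Camera was repeated with the correlation estimated from the residuals, and fry, which asks whether a list's genes move on balance one way, was run beside it. With an estimated correlation camera also rests on the residual degrees of freedom, so a lost list call need not come from correlation between its genes. Lists of columnar epithelium, squamous epithelium, fibroblasts and leukocytes served as cell type markers.

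Genes named at each time against 0 min were the 15 largest rises and the 10 largest falls among probe sets that passed with 1 symbol and had both low pH arrays beyond both 0 min arrays. Where fewer than 10 genes qualified in both directions together, the smallest unadjusted p-values were to fill the list, which was needed at no time. For each list, its 2 to 4 members with the largest absolute change were named as well. EGR1, FOS, JUN, ATF3, MYC, CXCL8, PTGS2, DDIT3, DUSP1 and CDKN1A were followed at every time. HSPA1A belonged to the same fixed genes but was not measured on its own, because its probe sets carried several symbols. The groups, comparisons, tests, filter, offset, lists, naming rule and alternatives were set before the data were examined, except where a later choice is stated.

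The alternatives were quantile normalisation, scaling by the array median, no offset, an offset at the 40th percentile, no filter, a filter on means above the 60th percentile, eBayes without the trend, the replicate number as a block, fits of only the groups compared, 1 probe set per gene, and leaving out each array in turn. Leaving out an array leaves its group with 1 array and the test with less power, so a call lost this way need not rest on that array. A test over other splits of the samples was not run, because groups of 2 arrays are too small for it. The steps were tested on simulated data made for 30 min against 0 min over 14963 probe sets. They recovered 6% of simulated log2 changes of 0.5, 62.7% of changes of 1 and 97% of changes of 2, with 3 of 113 calls among unchanged probe sets. With nothing changed, 5 runs of the 7 comparisons gave 6 calls in all. A simulated log2 shift of 0.3 in 1 list over 8913 genes gave that list a camera adjusted p of 1.92e-10 and 0 of 27 unshifted lists passed. The simulated noise was independent between genes, so this cannot show how often camera calls lists whose genes vary together. R 4.3.3 and limma 3.58.1 were used for all tests, and Python 3.11.15 with matplotlib 3.10.9 for the figures.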

Results

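The series asked which genes respond when oesophageal SKGT4 cells are exposed to low pH. It held 10 arrays in 5 groups of 2, resting cells at 0 min and cells at pH 6.5 for 30, 120, 180 or 240 min. Median signals lay between 35.9 and 44 units on arrays scaled to a trimmed mean of 100. Any 2 arrays correlated across probe sets, which are not independent replicates, at r between 0.931 and 0.976 on the log2 scale. Arrays of one time correlated at 0.9665 to 0.9756, except the pair at 180 min at 0.944. Replicate 1 at 180 min had the highest median, 44, the highest share of probe sets above the filter, 64% against 57.6% to 60.6% on the others, and the lowest mean correlation with the other arrays, 0.9379 against 0.9594 to 0.9655.

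The number of arrays limited the precision. No source used here says that the replicates were separate cultures, so the p-values of genes measure only the spread between these arrays, which may be technical. Those of camera at its preset correlation set a list's genes against the other genes and measure mostly the spread between genes. The only untreated samples were the 0 min ones, so every change is a change with time at low pH and includes any effect of handling or of time in culture. With no detection calls, folds from baselines near background depend on the offset, as for FOSB (12.6 units at 0 min), AK5 (5.7), ALOX12P2 (5.7) and NR4A3 (5.35), and for FOS at 120 min (4.35). Log2 changes are given with the standard error of the fit, and signals as mean and SD, n = 2 arrays per group throughout.

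Over the time course, 442 probe sets of 288 genes changed by limma's moderated F test. Against 0 min, 51 genes rose and 1 fell at 30 min, 138 rose and 21 fell at 120 min, 93 rose and 22 fell at 180 min, and 200 rose and 92 fell at 240 min. Among probe sets at 180 min, rises outnumbered falls without replicate 1, but not without replicate 2, where the outlying replicate 1 stood alone. Among the 288 genes, the largest change came at 240 min for 104 that were higher and 55 that were lower there. At 120 min it came for 62 that were higher and 19 that were lower.

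**Figure D1:**
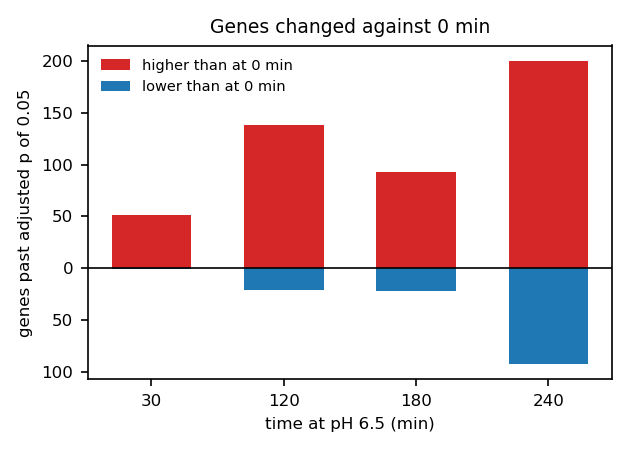
Number of genes past the threshold against 0 min (y axis, genes, bars from 0) at 30, 120, 180 and 240 min at pH 6.5 (x axis, evenly spaced), with separate bars for genes higher and lower. Rises outnumbered falls at each time, by 51 to 1 at 30 min and by 200 to 92 at 240 min. For probe sets at 180 min this held without replicate 1 but not without replicate 2.

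The first comparison, 30 min against 0 min, asked which genes responded early. Transcription factor genes of the immediate early class were 15 of the 51 genes that rose. FOSB rose by 5.41 ± 0.16 on the log2 scale, from 12.6 ± 5.4 to 841 ± 63 units (adjusted p = 1e-09). FOS, which like FOSB forms AP-1 with JUN proteins, rose by 4.11 ± 0.19, from 24.8 ± 0.92 to 555 ± 84 units (adjusted p = 4.4e-08). ATF3, a stress-induced factor, rose by 3.30 ± 0.11, from 50.4 ± 1.6 to 563 ± 35 units (adjusted p = 2.7e-09). DUSP1, a phosphatase that switches off MAP kinases, rose by 3.43 ± 0.15, from 102 ± 2.6 to 1180 ± 160 units (adjusted p = 2.8e-08). Its second probe set passed at no time (2.29 ± 0.56, adjusted p = 0.18). The matricellular gene CCN2 rose by 2.49 ± 0.11, from 265 ± 24 to 1520 ± 130 units, and its relative CCN1 by 1.90 ± 0.17. EGR3 rose by 2.64 ± 0.18, EGR1 by 1.73 ± 0.15, NR4A1 by 2.06 ± 0.17, NR4A2 by 1.77 ± 0.19 and FOSL1 by 1.88 ± 0.18, all transcription factors. Endothelin 1 (EDN1) rose by 2.34 ± 0.15. DUSP5 rose by 2.19 ± 0.11 and the pseudokinase gene TRIB1 by 1.73 ± 0.13. JUN rose by 1.14 ± 0.12. The chemokine gene CXCL8 rose by 1.46 ± 0.15, from 723 ± 120 to 2000 ± 170 units, and PTGS2, which encodes a prostaglandin synthase, by 1.34 ± 0.15. MYC (0.35 ± 0.15, adjusted p = 0.82), DDIT3 (-0.24 ± 0.16, adjusted p = 0.94) and CDKN1A (0.04 ± 0.15, adjusted p = 1) did not pass. Nor did 1 more probe set each of NR4A1 (0.72 ± 0.32, adjusted p = 0.83) and JUN (0.65 ± 0.18, adjusted p = 0.3).

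In this comparison limma called 76 probe sets, 74 higher and 2 lower. The count of falls was 1 without any 1 of the 0 or 120 min arrays, 12 without 30 min replicate 2 and 4 without either 180 min array. Of the rises, 30 of the 51 genes that rose did so by more than 2-fold. The adenylate kinase gene AK5 rose by 1.78 ± 0.34 (adjusted p = 0.032) and RHBDF2, the only gene that fell, by -0.71 ± 0.14 (adjusted p = 0.044). Both calls were lost without any 1 of the 0, 30, 120 or 240 min arrays. AK5 then had adjusted p = 0.14 and 0.19 without the 0 min replicates 1 and 2, 0.12 and 0.32 without those at 30 min, 0.08 and 0.073 without those at 120 min, and 0.071 and 0.065 without those at 240 min (range over all alternatives 0.0079 to 0.32). RHBDF2 had 0.45 and 0.13, 0.18 and 0.19, 0.085 and 0.086, and 0.073 and 0.076 in the same order (range over all alternatives 0.033 to 0.45).

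Among the lists at 30 min, 15 of 28 measured immediate early transcription factors rose, 0 fell and 13 did not pass, with 19 higher and 0 lower adjusted over the list alone. The list's median change was 0.81 and camera put it above other genes (adjusted p = 1.4e-55). Of 30 other immediate early genes, 13 rose and 17 did not pass (21 adjusted over the list alone). CCN2, EDN1, CCN1 and TRIB1 led them (median 0.61, camera adjusted p = 1.3e-44). Of 26 NF-kappaB targets, 4 rose and 22 did not pass (8 adjusted over the list alone). CXCL8, PTGS2 and the chemokine gene CCL20 (0.93 ± 0.14) were among them, while TRAF1 at 1.47 ± 0.45 did not pass (adjusted p = 0.45; list median 0.35, camera adjusted p = 3.4e-14). CCL20 lost its call without 0 min replicate 2 (adjusted p = 0.088) or 30 min replicate 2 (adjusted p = 0.053; range over alternatives 0.0013 to 0.1). Of 14 MAP kinase phosphatases and feedback inhibitors, DUSP1 and DUSP5 rose and 12 did not pass (3 adjusted over the list alone, camera adjusted p = 9.1e-05, adjusted p = 0.1 with an estimated correlation). Of 9 EGF receptor ligands and receptors, HBEGF rose by 1.45 ± 0.24 and EREG by 0.80 ± 0.12, and 7 did not pass (2 adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.11 with an estimated correlation). That list's call was lost without 0 min replicate 2 (adjusted p = 0.13) or 30 min replicate 2 (adjusted p = 0.14; range over alternatives 0.0069 to 0.14). HBEGF lost its call without 0 min replicate 2 (adjusted p = 0.1) or 30 min replicate 1 (adjusted p = 0.14; range 0.0014 to 0.14). EREG lost it without 0 min replicate 2 (adjusted p = 0.091; range 0.0025 to 0.091).

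The second comparison, 120 min against 0 min, showed a changed set of genes. FOSB stayed high at 297 ± 14 units (3.93 ± 0.16, adjusted p = 2.9e-08), and FOSL1, another AP-1 subunit, rose by 2.79 ± 0.18, from 101 ± 11 to 746 ± 33 units (adjusted p = 2.8e-06). CCN2 rose by 2.79 ± 0.11 to 1870 ± 39 units and CCN1 by 2.20 ± 0.17. The tight junction gene CLDN4 rose by 2.52 ± 0.16, from 42.2 ± 4.5 to 278 ± 2.6 units (adjusted p = 2.6e-06). The transcribed pseudogene ALOX12P2 rose by 2.51 ± 0.29 (adjusted p = 0.00029). MAFF rose by 2.24 ± 0.11, EDN1 by 1.82 ± 0.15, TMEM158 by 1.77 ± 0.18 and ATF3 by 1.75 ± 0.11. The Wnt receptor gene FZD7 rose by 1.74 ± 0.16, GLIPR1 by 1.71 ± 0.17 and the prostaglandin receptor gene PTGER4 by 1.69 ± 0.24. JUN rose by 0.86 ± 0.12, DUSP1 by 1.20 ± 0.15 and CXCL8 by 1.12 ± 0.15. PTGS2 (0.58 ± 0.15, adjusted p = 0.086), MYC (0.56 ± 0.15, adjusted p = 0.1), DDIT3 (-0.04 ± 0.16, adjusted p = 0.97) and CDKN1A (-0.34 ± 0.15, adjusted p = 0.39) did not pass. NR4A3 rose by 1.77 ± 0.33 (adjusted p = 0.012) and the interleukin 33 receptor gene IL1RL1 by 1.83 ± 0.39 (adjusted p = 0.03). Of other probe sets, 2 of NR4A3 (1.30 ± 0.39 and 0.01 ± 0.40, adjusted p = 0.15 and 1), 1 of GLIPR1 (0.92 ± 0.24, adjusted p = 0.083) and 1 of JUN (0.33 ± 0.18, adjusted p = 0.53) did not pass. Both NR4A3 and IL1RL1 depended on single arrays. NR4A3 had adjusted p = 0.084 and 0.069 without the 0 min replicates 1 and 2 and 0.055 and 0.17 without those at 120 min (range over alternatives 0.0077 to 0.17). IL1RL1 had 0.26, 0.079, 0.26 and 0.17 in the same order (range 0.0047 to 0.26).

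FOS and EGR1, both high at 30 min, lay below their resting level at 120 min. FOS fell by -1.44 ± 0.19, from 24.8 ± 0.92 to 4.35 ± 2.5 units (adjusted p = 0.00089), a level below the offset. Its change was -2.64 with no offset and -0.76 with the larger one, and passed with both (adjusted p = 0.00057 and 0.012). It had adjusted p = 0.2 with only the 4 arrays compared in the fit (range over alternatives 0.00057 to 0.2). EGR1 fell by -1.0 ± 0.15, from 111 ± 0.49 to 52.1 ± 6.1 units (adjusted p = 0.0032), with adjusted p = 0.055 without 120 min replicate 1 (range 0.0022 to 0.055). Its second probe set did not pass (0.27 ± 0.20, adjusted p = 0.68). DDIT4, an inhibitor of mTOR signalling, fell by -1.10 ± 0.11, from 566 ± 11 to 261 ± 5.4 units (adjusted p = 9.6e-05). PIK3IP1, an inhibitor of PI3 kinase, fell by -1.01 ± 0.12 (adjusted p = 0.00041). TXNIP, which responds to glucose, fell by -0.87 ± 0.15, from 1340 ± 120 to 726 ± 7.4 units. DUSP6 fell by -1.40 ± 0.25, LOC100505915 by -1.14 ± 0.24, FZD5 by -0.97 ± 0.17, NCK1 by -0.84 ± 0.15 and BCL6 by -0.83 ± 0.16. Second probe sets of DUSP6 (-0.66 ± 0.24, adjusted p = 0.26) and BCL6 (-0.69 ± 0.20, adjusted p = 0.15) did not pass. These 6 calls were lost when single arrays were left out. TXNIP lost its call without 0 min replicate 1 (adjusted p = 0.099) or 120 min replicate 1 or 2 (0.067 and 0.075; range over alternatives 0.0028 to 0.099). DUSP6 lost it without 0 min replicate 2 (0.14) or 120 min replicate 1 or 2 (0.064 and 0.093; range 0.003 to 0.14). FZD5 lost it without the same arrays (0.11, 0.081 and 0.06; range 0.0053 to 0.11). LOC100505915 lost it without 0 min replicate 1 or 2 (0.26 and 0.093) or 120 min replicate 2 (0.24; range 0.017 to 0.26). BCL6 lost it without the same arrays (0.059, 0.17 and 0.17; range 0.0093 to 0.17). NCK1 lost it without 0 min replicate 2 (0.14) or 120 min replicate 1 (0.18; range 0.0067 to 0.18). In all, limma called 263 probe sets at 120 min, 224 higher and 39 lower. The count was 149 and 123 without the 0 min replicates 1 and 2, and 118 without either 120 min array, and the falls were 11, 10, 13 and 14 in that order.

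Genes of the actin cytoskeleton and of serum response factor were higher as a list at 120 min. Of 18 measured, 6 rose and 12 did not pass (12 higher adjusted over the list alone), with a median of 0.52 and camera adjusted p = 2.4e-16. CCN2 and CCN1 led, followed by FILIP1L at 1.24 ± 0.26 and FHL2 at 0.98 ± 0.10. FILIP1L lost its call without 0 min replicate 1 or 2 (adjusted p = 0.23 and 0.063) or 120 min replicate 1 or 2 (0.21 and 0.15; range over alternatives 0.018 to 0.23). Of the immediate early transcription factors, 12 rose and 13 did not pass (19 higher and 5 lower adjusted over the list alone, median 0.64, camera adjusted p = 5.2e-15). The 3 that fell were FOS, EGR1 and HES1 (-0.80 ± 0.12, with adjusted p = 0.054 without 0 min replicate 2; range 0.0018 to 0.054). Of the other immediate early genes, 11 rose and 19 did not pass (17 higher and 3 lower adjusted over the list alone, camera adjusted p = 4.1e-17). Of 10 Wnt pathway targets, FZD7, SOX9 (1.16 ± 0.14) and JUN rose and 7 did not pass (5 adjusted over the list alone, median 0.44, camera adjusted p = 1.3e-07). Of 25 sterol synthesis and uptake genes, 3 rose and 22 did not pass (4 higher and 1 lower adjusted over the list alone). These were INSIG1 at 1.66 ± 0.16, HMGCS1 at 0.98 ± 0.15 and IDI1 at 0.92 ± 0.15, with camera adjusted p = 0.029 for the list and adjusted p = 0.27 with an estimated correlation. The sterol list's call was lost without 0 min replicate 1 (adjusted p = 0.14) or 120 min replicate 1 (adjusted p = 0.2). HMGCS1 lost its call without 120 min replicate 1 (0.059; range over alternatives 0.0018 to 0.059) and IDI1 without 0 min replicate 1 (0.066) or 120 min replicate 1 (0.081; range 0.0026 to 0.081).

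Of 23 cell adhesion and junction genes at 120 min, CLDN4, ITGA2 (1.13 ± 0.21) and TJP1 (0.55 ± 0.12) rose and 20 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00044). ITGA2 lost its call without 0 min replicate 1 or 2 (adjusted p = 0.057 and 0.13) or 120 min replicate 2 (0.15; range over alternatives 0.0035 to 0.15). TJP1 lost it without any 1 of the 0, 120 or 240 min arrays (0.32 and 0.053, 0.25 and 0.16, 0.062 and 0.062, replicates 1 and 2 in turn; range 0.018 to 0.32). Of 19 squamous epithelium genes, 4 rose and 15 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00063), led by the keratin gene KRT16 at 1.31 ± 0.12 (adjusted p = 3.6e-05). Of 16 columnar epithelium genes, GATA6 rose by 1.31 ± 0.20 (adjusted p = 0.0031) and 15 did not pass (1 adjusted over the list alone, camera adjusted p = 0.6). BMP2 was the 1 of 19 TGF-beta and BMP targets that rose, by 1.35 ± 0.21 (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.068). The EGF receptor list had 3 rises, HBEGF, EREG and TGFA, and 6 members that did not pass (4 adjusted over the list alone, camera adjusted p = 1e-04). EREG had the largest change, 1.11 ± 0.12. HBEGF lost its call without 0 min replicate 2 (adjusted p = 0.3), 120 min replicate 1 or 2 (0.28 and 0.14) or 240 min replicate 1 or 2 (0.066 and 0.067; range 0.005 to 0.3). TGFA, of whose 2 other probe sets 0 passed with a rise and 1 had the opposite sign, lost it without 0 min replicate 1 or 2 (0.2 and 0.052) or 120 min replicate 1 or 2 (0.092 and 0.16; range 0.01 to 0.2). Of the MAP kinase feedback list, 3 rose, DUSP1, DUSP5 and DUSP14 (0.97 ± 0.14), DUSP6 fell and 10 did not pass (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0069, adjusted p = 0.2 with an estimated correlation). Of the NF-kappaB targets, 4 rose and 22 did not pass (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0026).

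The third comparison, 180 min against 0 min, again had early genes among its largest rises. FOSB was at 794 ± 80 units (5.32 ± 0.16, adjusted p = 1.2e-09) and ATF3 at 622 ± 43 units (3.44 ± 0.11, adjusted p = 1.6e-09). FOS rose by 2.12 ± 0.19 against 0 min, to 134 ± 0.14 units (adjusted p = 3.2e-05), and EGR1 by 1.20 ± 0.15. EGR3 (2.81 ± 0.18), FOSL1 (2.79 ± 0.18), NR4A1 (2.14 ± 0.17), NR4A2 (1.91 ± 0.19) and MAFF (1.95 ± 0.11) rose as well. Another probe set of NR4A1 did not pass (-0.45 ± 0.32, adjusted p = 0.63). DUSP1 rose by 2.43 ± 0.15 and DUSP5 by 1.89 ± 0.11. CCN2 rose by 2.73 ± 0.11, CCN1 by 2.35 ± 0.17, EDN1 by 2.23 ± 0.15 and CLDN4 by 1.97 ± 0.16. CYP1B1, a cytochrome P450 gene, entered the largest rises at 2.19 ± 0.12, from 105 ± 7.8 to 506 ± 24 units (adjusted p = 5.4e-07). JUN rose by 1.09 ± 0.12, CXCL8 by 1.58 ± 0.15 and PTGS2 by 1.39 ± 0.15. MYC (0.43 ± 0.15, adjusted p = 0.28), DDIT3 (-0.13 ± 0.16, adjusted p = 0.8) and CDKN1A (-0.23 ± 0.15, adjusted p = 0.59) did not pass.

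The falls at 180 min included EGLN3, a prolyl hydroxylase induced by hypoxia, at -1.06 ± 0.12, from 490 ± 3.2 to 231 ± 13 units (adjusted p = 0.00028). DDIT4 fell by -0.86 ± 0.11 (adjusted p = 0.00077). The endosomal GTPase gene RAB5C fell by -1.34 ± 0.18, from 362 ± 98 to 136 ± 10 units (adjusted p = 0.001). Another of its probe sets did not pass (-0.54 ± 0.19, adjusted p = 0.26). TRIB2 fell by -0.94 ± 0.14 and ANGPTL4 by -0.92 ± 0.14, the latter with adjusted p = 0.063 without 0 min replicate 2 (range over alternatives 0.0019 to 0.063). HMX1 fell by -1.76 ± 0.35, PBX2 by -1.25 ± 0.24, BTBD2 by -1.10 ± 0.22, BRD3 by -0.91 ± 0.16 and BCL6 by -0.90 ± 0.16, calls that were lost when single arrays were left out. Other probe sets of PBX2, TRIB2, BRD3 and BCL6 (-0.68 ± 0.20, adjusted p = 0.18) did not pass, nor did the second of MAFF (0.71 ± 0.18, adjusted p = 0.11), a gene that rose. HMX1 lost its call without 0 min replicate 1 or 2 (adjusted p = 0.057 and 0.29), 120 min replicate 1 or 2 (0.051 and 0.055) or 180 min replicate 1 (0.13; range 0.01 to 0.29). PBX2 lost it without 0 min replicate 1 or 2 (0.21 and 0.083) or 180 min replicate 2 (0.056; range 0.0086 to 0.21). BTBD2 lost it without 0 min replicate 1 or 2 (0.24 and 0.086) or 180 min replicate 1 (0.16; range 0.0049 to 0.24), BRD3 without the same arrays (0.094, 0.12 and 0.1; range 0.0048 to 0.12). BCL6 lost it without 0 min replicate 2 (0.14) or 180 min replicate 1 (0.098; range 0.0063 to 0.14). In all, limma called 177 probe sets, 146 higher and 31 lower. The count was 112 and 101 without the 0 min replicates 1 and 2 (8 and 9 lower), 126 without 180 min replicate 1 (18 lower) and 490 without 180 min replicate 2 (303 lower), of which 38.2% were higher. Without 180 min replicate 1, 69 of the 93 genes that rose kept their calls, and 10 of the 22 that fell.

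The metallothionein and zinc transport list moved at 180 min. Of 9 measured genes, MT1E (1.31 ± 0.13, adjusted p = 6.5e-05) and the zinc exporter gene SLC30A1 (0.93 ± 0.11, adjusted p = 0.00046) rose and 7 did not pass (6 adjusted over the list alone), with a median of 0.45 and camera adjusted p = 1.9e-07. Of 30 hypoxia and glycolysis genes, EGLN3, ANGPTL4 and DDIT4 fell and 27 did not pass (1 higher and 7 lower adjusted over the list alone, median -0.24, camera adjusted p = 8.1e-07). Of the immediate early transcription factors, 18 rose and 10 did not pass (23 higher and 1 lower adjusted over the list alone, median 0.90, camera adjusted p = 3.5e-37). The other immediate early genes had 16 rises and 14 that did not pass (20 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.9e-28), with TRIB1 at 1.58 ± 0.13. NF-kappaB targets had 6 rises and 20 that did not pass (12 adjusted over the list alone, median 0.54, camera adjusted p = 1.4e-09). Their largest changes were those of CXCL8, PTGS2 and TRAF1 (1.57 ± 0.45, adjusted p = 0.16). Actin and serum response factor genes had 4 rises and 14 that did not pass (8 adjusted over the list alone, camera adjusted p = 7.9e-11), with FHL2 at 0.69 ± 0.10. Of the Wnt targets, FZD7 (1.18 ± 0.16) and JUN rose and 8 did not pass (4 adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.064 with an estimated correlation). The EGF receptor list had 2 rises, HBEGF at 1.43 ± 0.24 and EREG at 1.00 ± 0.12, and 7 that did not pass (3 adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.064 with an estimated correlation). HBEGF had adjusted p = 0.067 without 0 min replicate 2 (range over alternatives 0.0011 to 0.082). Of 19 squamous genes, KRT16 (0.78 ± 0.12) and SPRR3 (0.99 ± 0.17) rose and 17 did not pass (2 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.13 with an estimated correlation). SPRR3 lost its call without 0 min replicate 2 (0.12) or 180 min replicate 1 (0.089; range 0.0067 to 0.12), and the squamous list lost its own without those arrays (0.21 and 0.07) or 180 min replicate 2 (0.11). Of the MAP kinase feedback list, 3 rose, DUSP1, DUSP5 and DUSP14 (0.97 ± 0.14), and 11 did not pass (5 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.29 with an estimated correlation). That list's call was lost without 0 min replicate 1 (0.064) or 180 min replicate 2 (0.74), and its median of 0.01 was -0.09 with median scaling.

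The fourth comparison, 240 min against 0 min, had the most changes. FOSB was at 788 ± 59 units (5.31 ± 0.16, adjusted p = 1.1e-09), ATF3 at 674 ± 22 units (3.55 ± 0.11, adjusted p = 1.1e-09) and CCN2 at 1990 ± 96 units (2.88 ± 0.11, adjusted p = 6e-09). MT1E, a metal-binding protein gene, rose by 2.27 ± 0.13, from 352 ± 30 to 1730 ± 43 units (adjusted p = 2.3e-07), and CYP1B1 by 2.58 ± 0.12 to 667 ± 6.9 units (adjusted p = 6.8e-08). EGR3 rose by 2.97 ± 0.18, FOSL1 by 2.96 ± 0.18, DUSP1 by 2.88 ± 0.15 and EDN1 by 2.76 ± 0.15. NR4A1 rose by 2.69 ± 0.17, NR4A3 by 2.65 ± 0.33, CCN1 by 2.54 ± 0.17, NR4A2 by 2.21 ± 0.19, MAFF by 2.18 ± 0.11 and TMEM158 by 2.12 ± 0.18. FOS rose by 1.69 ± 0.19, JUN by 1.66 ± 0.12, EGR1 by 1.04 ± 0.15, CXCL8 by 1.22 ± 0.15 and PTGS2 by 1.81 ± 0.15. MYC rose by 0.87 ± 0.15 (adjusted p = 0.0051), a call lost without 0 min replicate 1 (adjusted p = 0.054) or 240 min replicate 2 (adjusted p = 0.082; range over alternatives 0.0011 to 0.082). Other probe sets of NR4A1 (0.33 ± 0.32, adjusted p = 0.76) and NR4A3 (0.42 ± 0.40, adjusted p = 0.74) did not pass, and DDIT3 (0.09 ± 0.16, adjusted p = 0.88) and CDKN1A (-0.13 ± 0.15, adjusted p = 0.8) did not pass either.

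Among the falls at 240 min was that of FOXM1, a driver of mitotic genes, by -1.18 ± 0.18, from 166 ± 4.7 to 69.5 ± 13 units (adjusted p = 0.002). The chromatin gene ATAD2 fell by -1.22 ± 0.14, from 274 ± 29 to 113 ± 1.2 units (adjusted p = 0.00016), and the helicase gene HELLS by -1.15 ± 0.18 (adjusted p = 0.0023). EGLN3 fell by -1.40 ± 0.12 to 181 ± 17 units (adjusted p = 1.2e-05) and the nuclear receptor gene NR2F6 by -1.17 ± 0.17 (adjusted p = 0.0011). The enolase gene ENO2 fell by -1.28 ± 0.21 (adjusted p = 0.0034), with adjusted p = 0.057 without 240 min replicate 2 (range over alternatives 0.0016 to 0.057). SPN fell by -1.38 ± 0.30, COQ8A by -1.34 ± 0.33, CDH5 by -1.32 ± 0.24 and NBL1 by -1.31 ± 0.31, calls that depended on single arrays. SPN lost its call without 0 min replicate 1 or 2 (adjusted p = 0.24 and 0.084) or 240 min replicate 1 or 2 (0.22 and 0.058; range 0.022 to 0.24). CDH5 lost it without 0 min replicate 1 or 2 (0.062 and 0.098) or 240 min replicate 2 (0.085; range 0.0048 to 0.098). COQ8A lost it without any 1 of the 0, 30, 120 or 240 min arrays (0.052 and 0.37, 0.069 and 0.064, 0.073 and 0.077, 0.25 and 0.14, replicates 1 and 2 in turn; range 0.026 to 0.37). NBL1 lost it without 0 min replicate 1 or 2 (0.21 and 0.2), 120 min replicate 1 or 2 (0.053 and 0.054) or 240 min replicate 2 (0.37; range 0.014 to 0.37). In all, limma called 441 probe sets, 312 higher and 129 lower, so that 70.7% were higher, against 82% when arrays were scaled to the median. The count was 238 and 243 without the 0 min replicates 1 and 2, and 225 and 219 without those at 240 min, and the falls were 37, 48, 50 and 49 in that order.

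Cell cycle genes were lower as lists at 240 min. Of 33 genes of the G1 to S phase and DNA replication, 6 fell, 0 rose and 27 did not pass (18 lower adjusted over the list alone), with a median of -0.42 and camera adjusted p = 1.2e-11. RRM2, a subunit of ribonucleotide reductase, fell by -0.83 ± 0.12 (adjusted p = 0.00082) and the replication clamp gene PCNA by -0.81 ± 0.19 (adjusted p = 0.038). Of 32 G2 to M phase genes, 7 fell, 0 rose and 25 did not pass (20 lower adjusted over the list alone), with a median of -0.44 and camera adjusted p = 7.5e-11. The cyclin gene CCNA2 fell by -1.0 ± 0.19 (adjusted p = 0.0099) and CDK1 by -0.79 ± 0.13 (adjusted p = 0.0041). PCNA lost its call without 0 min replicate 1 or 2 (adjusted p = 0.26 and 0.13), 120 min replicate 1 or 2 (0.06 and 0.06) or 240 min replicate 1 (0.33; range over alternatives 0.003 to 0.33). CCNA2 lost it without 0 min replicate 2 or 240 min replicate 1 (0.14 and 0.14; range 0.0055 to 0.14). CDK1 lost it without the same arrays (0.053 and 0.058; range 0.0022 to 0.058). With median scaling 2 and 3 members of these lists fell, and the medians were -0.38 and -0.39. At 30, 120 and 180 min, limma called 0 members of either list. In the G1 to S list 1 member was lower at an unadjusted p under 0.05 at 30 and at 120 min and 1 higher at 180 min (camera adjusted p = 0.53, 0.2 and 0.64). In the G2 to M list 0, 6 and 3 were lower at an unadjusted p under 0.05, and 1 was higher at 180 min. The G2 to M median was -0.22 at 120 min (camera adjusted p = 0.00032) and -0.16 at 180 min (camera adjusted p = 0.028, adjusted p = 0.094 with an estimated correlation), and the call at 180 min was lost without 0 min replicate 1 (0.064) or 180 min replicate 1 or 2 (0.057 and 0.1).

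**Figure D2:**
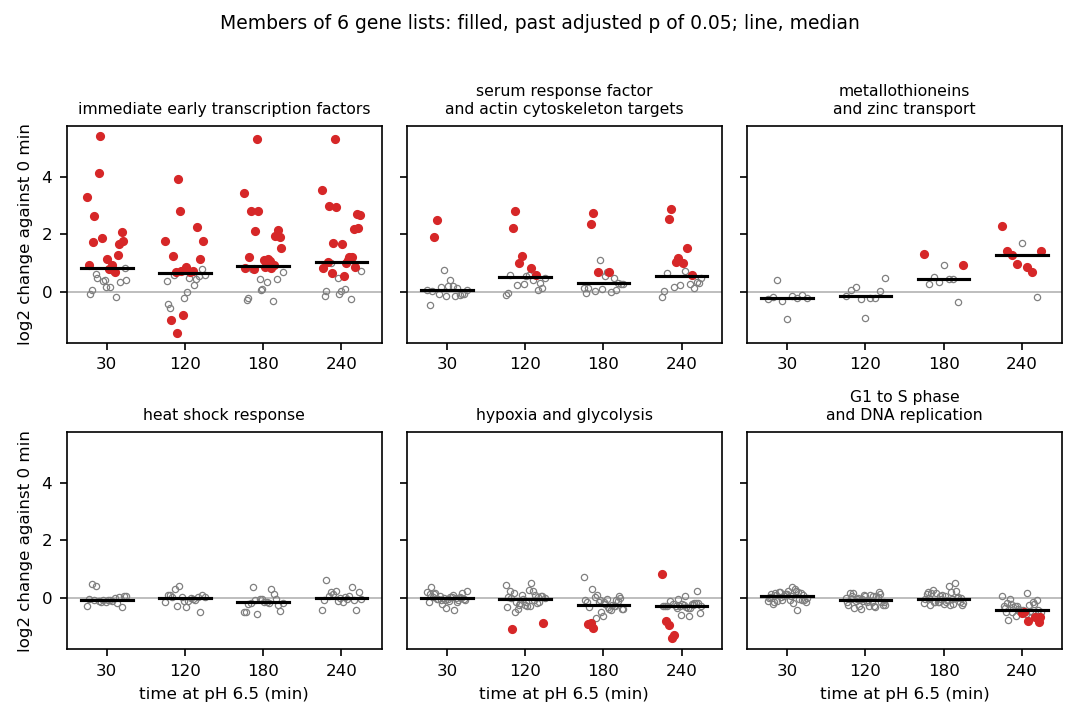
Log2 change against 0 min (y axis) of the measured members of 6 gene lists at 30, 120, 180 and 240 min at pH 6.5 (x axis). Each point is a gene, filled where it passed, and the line is the list's median, which reached 1.29 for metallothioneins and -0.42 for G1 to S genes at 240 min and stayed between -0.16 and 0.01 for heat shock genes.

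Metallothioneins rose as a list at 240 min. Of the 9 genes, 7 rose and 2 did not pass (8 adjusted over the list alone), with a median of 1.29 and camera adjusted p = 2.6e-16. After MT1E came SLC30A1 at 1.40 ± 0.11 and MT1F at 1.40 ± 0.14, while MT1M at 1.69 ± 0.56 did not pass (adjusted p = 0.16). Metallothionein transcripts are alike in sequence, so probe sets of this family may share signal. At 30 min the list's median was -0.21 with 0 calls by limma and 1 gene lower at an unadjusted p under 0.05. Camera gave it adjusted p = 0.012, lower, and adjusted p = 0.097 with an estimated correlation, a call lost without 0 min replicate 1 or 30 min replicate 1 (0.084 and 0.15). At 120 min the metallothioneins had 0 calls by limma, with 1 gene higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.61). Hypoxia and glycolysis genes had a median of -0.30 at 240 min. The list had 4 falls, EGLN3, ENO2, DDIT4 (-0.93 ± 0.11) and ANGPTL4, 1 rise, ADM at 0.83 ± 0.16, and 25 that did not pass (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 2.5e-08). ADM lost its call without 0 min replicate 1 (adjusted p = 0.14) or 240 min replicate 1 or 2 (0.065 and 0.12; range over alternatives 0.0082 to 0.14). ANGPTL4 lost it without 0 min replicate 2 (0.066) or 240 min replicate 2 (0.084; range 0.0028 to 0.084). At 120 min DDIT4 and TXNIP of that list fell and 28 did not pass (3 lower adjusted over the list alone, camera adjusted p = 0.071), and at 30 min 0 passed, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.99).

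Stress, signalling and growth lists also shifted at 240 min. The immediate early transcription factors had 19 rises and 9 that did not pass (22 adjusted over the list alone, median 1.02, camera adjusted p = 1e-36). The other immediate early genes also had 19 rises and 11 that did not pass (21 higher and 3 lower adjusted over the list alone, median 0.98, camera adjusted p = 1e-28). Actin and serum response factor genes had 7 rises and 11 that did not pass (10 adjusted over the list alone, camera adjusted p = 3.6e-16), with the smooth muscle gene TAGLN at 1.5 ± 0.14. Of the MAP kinase feedback list, 6 rose and 8 did not pass (7 adjusted over the list alone, camera adjusted p = 3.9e-08), with DUSP14 at 1.59 ± 0.14 and DUSP4 at 1.20 ± 0.19. The EGF receptor list had 3 rises, HBEGF at 2.02 ± 0.24, EREG at 0.91 ± 0.12 and TGFA at 0.76 ± 0.13, and 6 that did not pass (3 adjusted over the list alone, camera adjusted p = 6.1e-05). TGFA had adjusted p = 0.062 without 0 min replicate 1 (range over alternatives 0.0023 to 0.062). NF-kappaB targets had 8 rises, among them IL11 at 1.83 ± 0.27, 1 fall, TNFAIP2 at -0.86 ± 0.13, and 17 that did not pass (9 higher and 2 lower adjusted over the list alone, camera adjusted p = 5.5e-05). Of the Wnt targets, JUN, FZD7 (1.20 ± 0.16) and MYC rose and 7 did not pass (3 adjusted over the list alone, camera adjusted p = 3.2e-05). MYC's call there was lost without 0 min replicate 1 (0.054) or 240 min replicate 2 (0.082). Of 34 genes of the unfolded protein and integrated stress response, SLC7A11 (1.29 ± 0.13), PPP1R15A (1.25 ± 0.15) and SLC7A5 (0.47 ± 0.12) rose, DDIT4 fell and 30 did not pass (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00055). At 30, 120 and 180 min that list had 1, 0 and 1 rises and 0, 1 and 1 falls (1 higher and 0 lower, 1 and 1, and 1 and 1 adjusted over the list alone; camera adjusted p = 0.073, 0.45 and 0.11). PPP1R15A and DDIT4 were the genes that passed. SLC7A5 lost its call at 240 min without 0 min replicate 2 (0.38) or either array of 30 min (0.06 and 0.059), 120 min (0.074 and 0.073) or 240 min (0.23 and 0.24; range 0.01 to 0.38).

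Of 18 p53 targets, GADD45B rose at each time, by 1.20 ± 0.12 at 30 min and at 120 min, 1.42 ± 0.12 at 180 min and 1.56 ± 0.12 at 240 min. Of its 3 other probe sets 0, 1, 2 and 2 passed with a rise at these times. At 240 min GADD45A (1.17 ± 0.18) and PLK3 (1.02 ± 0.20) rose too and 15 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00043). PLK3 lost its call there without 0 min replicate 1 or 2 (adjusted p = 0.07 and 0.092) or 240 min replicate 1 or 2 (0.058 and 0.14; range over alternatives 0.0044 to 0.14). At 30, 120 and 180 min the p53 list had 1, 2 and 3 rises (2, 2 and 3 adjusted over the list alone) with camera adjusted p = 0.012, 0.071 and 0.038. It had adjusted p = 0.097 at 30 min and 0.13 at 180 min with an estimated correlation. The call at 30 min was lost without 30 min replicate 1. At 180 min it was lost without 0 min replicate 1 or 180 min replicate 2. Sterol genes had 5 rises at 240 min, among them INSIG1 at 1.28 ± 0.16, HMGCS1 at 0.88 ± 0.15 and IDI1 at 0.83 ± 0.15. The other 20 did not pass (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.14 with an estimated correlation). HMGCS1 lost its call without 0 min replicate 1 (0.058) or 240 min replicate 2 (0.063; range 0.0026 to 0.063). IDI1 lost it without 0 min replicate 1 (0.086) or 240 min replicate 1 (0.08; range 0.0035 to 0.086). INSIG1 was the sterol gene that rose at 180 min, by 1.16 ± 0.16 (2 adjusted over the list alone, camera adjusted p = 0.84). At 30 min 0 passed, with 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.66). TGF-beta and BMP targets had 2 rises at 240 min, BMP2 at 1.18 ± 0.21 and JUNB at 0.56 ± 0.13, and 17 that did not pass (4 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.06 with an estimated correlation). BMP2 lost its call there without 0 min replicate 2 (0.057) or 240 min replicate 1 (0.1; range 0.0017 to 0.1). JUNB lost it without 0 min replicate 1 or 2 (0.095 and 0.26) or 240 min replicate 1 or 2 (0.2 and 0.19; range 0.012 to 0.26). At 30 and 180 min JUNB was the member of that list that rose, by 0.80 ± 0.13 and 0.87 ± 0.13. Adjusted over the list alone 2 rose at 30 min, and 4 rose and 2 fell at 180 min. Camera gave adjusted p = 0.014 and 0.052, and 0.097 at 30 min with an estimated correlation. The call of the list at 30 min was lost without 0 min replicate 2 (0.067) or 30 min replicate 2 (0.057), and JUNB's without the same arrays (0.16 and 0.1; range 0.0049 to 0.19). JUNB lost its call at 180 min without 0 min replicate 2 (0.057; range 0.0014 to 0.067).

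Epithelial genes moved in part. At 240 min 5 squamous genes rose, 1 fell and 13 did not pass (5 higher and 1 lower adjusted over the list alone). KRT16 rose by 1.73 ± 0.12 (adjusted p = 1.3e-06), KRT14 by 1.34 ± 0.26 and SPRR3 by 1.04 ± 0.17, and KRT13 fell by -1.10 ± 0.13 (adjusted p = 0.00021). Camera gave the squamous list adjusted p = 0.0062, adjusted p = 0.057 with an estimated correlation, and 0.051 without 0 min replicate 2. KRT14 lost its call without 0 min replicate 2 (adjusted p = 0.13) or 240 min replicate 1 or 2 (0.065 and 0.14; range over alternatives 0.004 to 0.14). SPRR3 lost it without 0 min replicate 2 (0.053) or 240 min replicate 2 (0.073; range 0.0027 to 0.073). At 30 min limma called 0 squamous genes, with 2 higher at an unadjusted p under 0.05 (1 adjusted over the list alone, camera adjusted p = 0.12). Adhesion genes had 2 rises at 240 min, CLDN4 at 1.96 ± 0.16 and CLDN1 at 0.72 ± 0.13, and 21 that did not pass (4 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.06 with an estimated correlation, and 0.16 without 240 min replicate 2). CLDN1 lost its call without 0 min replicate 1 or 2 (0.075 and 0.052) or 240 min replicate 2 (0.12; range 0.0053 to 0.12). At 30 and 180 min CLDN4 was the adhesion gene that rose (1 adjusted over the list alone each time, camera adjusted p = 0.91 and 0.18). GATA6 was the columnar gene that rose at 240 min, by 1.24 ± 0.20 (1 adjusted over the list alone, camera adjusted p = 0.85). At 30 and 180 min limma called 0 columnar genes, with 0 and 1 at an unadjusted p under 0.05 (0 and 1 adjusted over the list alone, camera adjusted p = 0.23 and 0.26). Fibroblast markers had TAGLN as the 1 of 12 that rose, by 0.81 ± 0.14 at 120 min, 0.67 ± 0.14 at 180 min and 1.5 ± 0.14 at 240 min. Camera gave this list adjusted p = 0.91, 0.61, 0.24 and 0.087 in order of time, TAGLN was its 1 gene adjusted over the list alone at the 3 later times, and 1 was lower at an unadjusted p under 0.05 at 30 min. TAGLN lost its call at 120 min without 0 min replicate 1 or 2 (0.063 and 0.057) or 120 min replicate 1 or 2 (0.09 and 0.051; range 0.0043 to 0.09). At 180 min it lost it without 0 min replicate 1 or 2 (0.19 and 0.16), 120 min replicate 1 or 2 (0.059 and 0.057), 180 min replicate 2 (0.089) or 240 min replicate 1 or 2 (0.065 and 0.065; range 0.023 to 0.19). Of 10 leukocyte markers, limma called 0 at each time, with 1 higher at an unadjusted p under 0.05 at 30 min, 0 later and 0 adjusted over the list alone (camera adjusted p = 0.94, 0.94, 0.26 and 0.52).

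Several lists tied to acid or stress had few calls, and small changes may be missed. Of 24 heat shock genes 18 were measured, without HSPA1A. Limma called 0 at 30, 120, 180 and 240 min, with 1, 3, 4 and 3 at an unadjusted p under 0.05. After 30 min 0 passed adjusted over the list alone. DNAJB1 had 0.40 ± 0.10 at 30 min (adjusted p = 0.24), the 1 member higher adjusted over the list alone, and CRYAB 0.48 ± 0.35 (adjusted p = 0.95). Camera gave that list adjusted p = 0.55, 0.85, 0.052 and 0.71. At 180 min it passed, lower, without 0 min replicate 2 or any 1 of the 30 or 120 min arrays. Of 33 genes of pH regulation and proton sensing 19 were measured. Limma called 0 at 30, 120 and 180 min, with 1 lower at an unadjusted p under 0.05 each time. At 240 min the carbonic anhydrase gene CA2 rose by 1.61 ± 0.25 (adjusted p = 0.0019) and 18 did not pass (1 adjusted over the list alone). Camera gave this list adjusted p = 0.33, 0.7, 0.68 and 0.99. Of 25 NRF2 and oxidative stress genes, limma called 0 at 30 and 180 min, with 1 and 2 at an unadjusted p under 0.05. AKR1C2 fell by -0.60 ± 0.13 at 120 min and 24 did not pass. At 240 min SLC7A11 and GCLM (0.75 ± 0.19) rose, GPX2 fell by -0.70 ± 0.15 and 22 did not pass. The same members passed adjusted over the list alone, and camera gave adjusted p = 0.76, 0.11, 0.64 and 0.16. AKR1C2 lost its call without 0 min replicate 1 or 2 (adjusted p = 0.27 and 0.11), 120 min replicate 1 or 2 (0.055 and 0.27) or 240 min replicate 1 or 2 (0.059 and 0.059; range over alternatives 0.01 to 0.27). GPX2 lost it without 0 min replicate 1 or 2 (0.12 and 0.17) or 240 min replicate 1 (0.25; range 0.017 to 0.25). GCLM lost it without either array of 0 min (0.38 and 0.07), 120 min (0.056 and 0.054), 180 min (0.053 and 0.054) or 240 min (0.13 and 0.33; range 0.028 to 0.38). Among 24 apoptosis regulators the survival gene MCL1 rose at each time, by 0.89 ± 0.14, 0.80 ± 0.14, 0.70 ± 0.14 and 0.98 ± 0.14. TNFSF10, a death ligand, fell by -0.55 ± 0.13 at 120 min (adjusted p = 0.045) and by -1.03 ± 0.13 at 240 min (adjusted p = 0.00028). Adjusted over the list alone, 2, 1, 1 and 1 rose and 0, 1, 0 and 2 fell, and camera gave adjusted p = 0.32, 0.84, 0.42 and 0.85. TNFSF10 lost its call at 120 min without either array of 0 min (0.22 and 0.25), 120 min (0.37 and 0.12) or 240 min (0.074 and 0.075; range 0.025 to 0.37). MCL1 lost its call at 30 min without 0 min replicate 2 (0.091) or 30 min replicate 1 (0.072; range 0.00093 to 0.13). At 120 min it was lost without 0 min replicate 2 (0.079) or 120 min replicate 2 (0.098; range 0.0012 to 0.098), and at 180 min without 0 min replicate 1 or 2 (0.12 and 0.18) or 180 min replicate 2 (0.063; range 0.0035 to 0.18).

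Of 29 interferon response genes, OAS1 fell by -0.64 ± 0.13 at 240 min (2 lower adjusted over the list alone). Limma called 0 at 30, 120 and 180 min, with 0, 4 and 3 at an unadjusted p under 0.05. The list had camera adjusted p = 0.99, 0.01, 0.29 and 0.025, lower at 120 and 240 min. It had adjusted p = 0.068 at 120 min and adjusted p = 0.076 at 240 min with an estimated correlation. These calls were lost without 0 min replicate 2 (0.084 at 120 min and 0.14 at 240 min) and, at 240 min, without 240 min replicate 1 (0.1). OAS1 lost its call without 0 min replicate 1 (0.21) or 240 min replicate 1 or 2 (0.19 and 0.071; range over alternatives 0.012 to 0.21). Of 35 ribosomal protein genes limma called 0 at each time, with 1, 13, 1 and 3 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. RPL34 had the largest change at 120 min, -0.52 ± 0.14 (adjusted p = 0.091). Their medians were -0.11, -0.24, -0.02 and -0.16, with camera adjusted p = 0.00035, 3.3e-11, 0.4 and 0.004. With quantile normalisation the ribosomal medians were -0.07, -0.08, -0.05 and -0.06. These genes vary together between arrays, and the 3 calls had adjusted p = 0.56, 0.2 and 0.55 with an estimated correlation. The ribosomal call at 30 min was lost without 0 min replicate 1 (0.22) or 30 min replicate 2 (0.057), and that at 240 min without 0 min replicate 1 (0.23) or 240 min replicate 1 (0.39). At 180 min the ribosomal list passed without 0 min replicate 2 (0.037) or 180 min replicate 1 (0.00031). Of 38 oxidative phosphorylation genes limma called 0 at each time, with 2, 8, 3 and 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.0026, 6e-04, 0.078 and 0.35). It had adjusted p = 0.097 at 30 min and adjusted p = 0.062 at 120 min with an estimated correlation. Without 0 min replicate 1 these were 0.13 and 0.054, and at 180 min the list passed without 0 min replicate 2 (0.018). Of 26 proteasome genes limma called 0 at each time, with 1 lower at an unadjusted p under 0.05 at 120 min and 0 at the others, and 0 adjusted over the list alone (camera adjusted p = 0.4, 0.071, 0.29 and 0.71). Of the early lists not yet given, actin and serum response factor genes at 30 min had CCN2 and CCN1 as the 2 of 18 that rose (2 adjusted over the list alone). Camera gave adjusted p = 0.0075, adjusted p = 0.097 with an estimated correlation, and 0.11 without 30 min replicate 2. Wnt targets at 30 min had JUN as the 1 of 10 that rose (3 adjusted over the list alone, camera adjusted p = 0.00024, adjusted p = 0.059 with an estimated correlation).

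Among the list members given above, besides those already noted, 0 of the other probe sets of the gene passed in the same direction for HBEGF at 30 min, AKR1C2, INSIG1, TNFSF10 and TJP1 at 120 min, INSIG1 at 180 min, and DUSP4, TGFA, IL11, PLK3 and OAS1 at 240 min. Across the 28 lists and 4 times, 57 of 112 combinations passed with camera, 43 higher and 14 lower. With an estimated correlation, which for some lists that lost calls lay below the preset 0.01 (-0.048 for p53 targets), 31 passed. Among them were the immediate early lists and the NF-kappaB targets at each time, the actin and serum response factor genes at 120, 180 and 240 min, the metallothioneins and the hypoxia genes at 180 and 240 min, and both cell cycle lists at 240 min. In lists that did not pass, the median lay below 0 where camera put the list above other genes for sterol genes at 180 min (-0.02), apoptosis regulators at 240 min (-0.04), columnar genes at 240 min (-0.05), NRF2 genes at 180 min (-0.01), leukocyte markers at 30 and 120 min (-0.01 and -0.07), proteasome genes at 240 min (-0.03) and adhesion genes at 30 min (-0.01). Another scaling changed the sign of such small medians for NRF2 genes at 180 min (0.01 with quantile normalisation), pH regulation genes at 240 min (0.01 with median scaling), sterol genes at 180 min (0.01 with quantile normalisation), apoptosis regulators at 30 and 240 min (-0.01 and 0.01 with median scaling) and columnar genes at 240 min (0.04 with quantile normalisation). With median scaling it also changed for squamous genes at 30 min (-0.01), fibroblast markers at 180 min (-0.03), proteasome genes at 240 min (0.02) and adhesion genes at 180 min (-0.06).

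**Figure D3:**
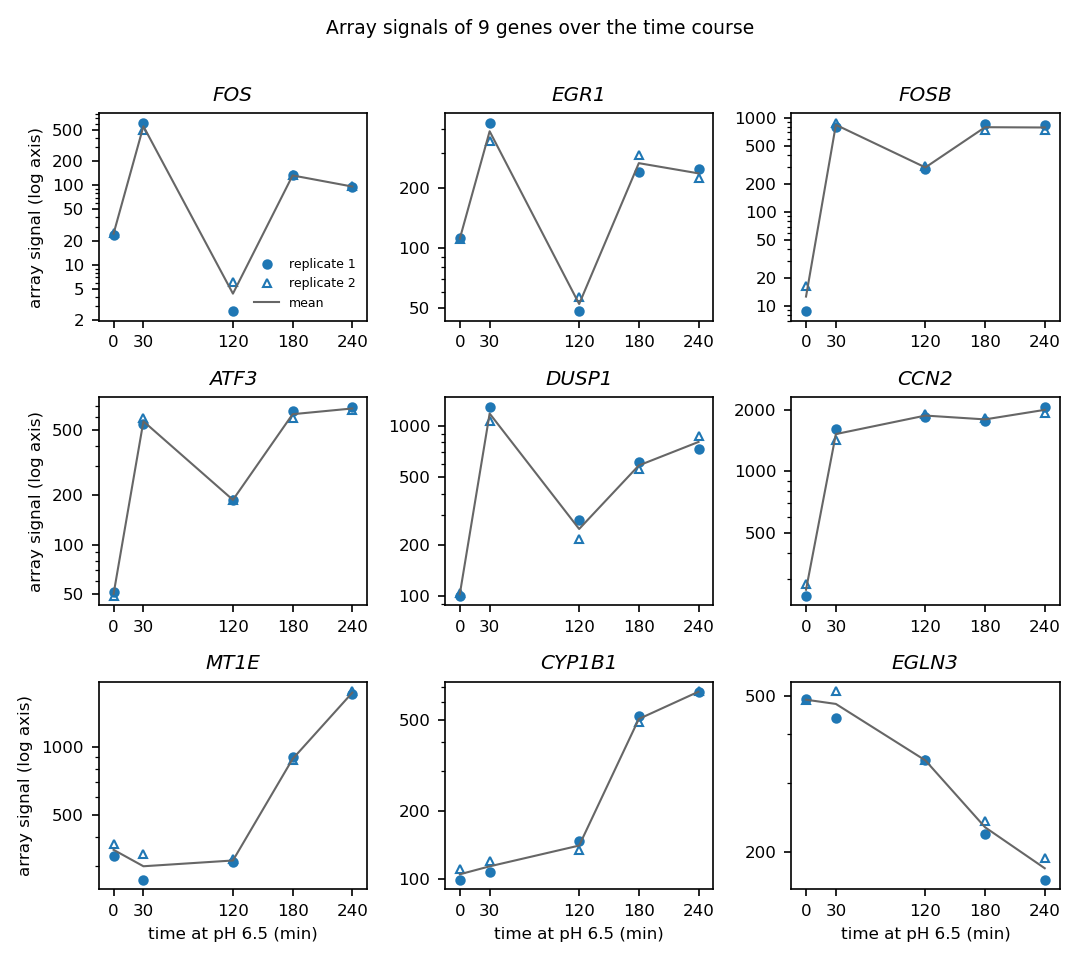
Signal on each array (y axis, units, log scale) of 9 genes against time at pH 6.5 (x axis, min), with 2 arrays per time as points and a line through the means. FOS went from 555 units at 30 min to 4.35 at 120 min and 134 at 180 min, while MT1E reached 1730 units at 240 min and EGLN3 fell to 181.

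The last comparisons set neighbouring times against each other, which tests directly whether the response changed. From 30 to 120 min FOS fell by -5.55 ± 0.19 (adjusted p = 4.8e-09; -7.11 with no offset and -4.29 with the larger one) and EGR1 by -2.72 ± 0.15 (adjusted p = 1.3e-06). DUSP1 fell by -2.23 ± 0.15 (adjusted p = 6.2e-06) and ATF3 by -1.55 ± 0.11 (adjusted p = 1.8e-05), while CLDN4 rose by 1.24 ± 0.16 (adjusted p = 0.0017). Of the 28 immediate early transcription factors 10 fell and 2 rose (5 higher and 14 lower adjusted over the list alone, median -0.31). From 120 to 180 min FOS rose by 3.57 ± 0.19 (adjusted p = 1.3e-06; 5.07 with no offset and 2.42 with the larger one), EGR1 by 2.20 ± 0.15, ATF3 by 1.69 ± 0.11 and CYP1B1 by 1.80 ± 0.12 (adjusted p = 9.1e-06 for each). Of the 28 factors 9 rose and 0 fell, with 2 lower at an unadjusted p under 0.05 (12 higher and 2 lower adjusted over the list alone). MT1E rose by 1.46 ± 0.13 over the same step (adjusted p = 6.8e-05) and by 0.96 ± 0.13 from 180 to 240 min (adjusted p = 0.0099). The later rise was lost without 180 min replicate 1 or either array of 240 min. Of the G1 to S genes, RRM2 fell from 180 to 240 min by -0.82 ± 0.12 (adjusted p = 0.011), 16 were lower adjusted over the list alone and the median was -0.44. RRM2 lost this call without 180 min replicate 1 (0.11) or either array of 240 min (0.12 and 0.15; range over single arrays left out 0.0086 to 0.15). Of the 28 factors limma called 0 from 180 to 240 min, with 5 higher and 2 lower at an unadjusted p under 0.05.

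Limma called 169 probe sets between 30 and 120 min (110 higher, 59 lower), 87 between 120 and 180 min (43 higher, 44 lower) and 36 between 180 and 240 min (20 higher, 16 lower). From 30 to 120 min the count was 101 and 84 without the 30 min replicates 1 and 2, and 68 and 47 without those at 120 min, where 48.5% and 40.4% of the calls were higher against 65.1%. From 120 to 180 min it was 27 and 32 without the 120 min replicates, 34 without 180 min replicate 1, 592 without 180 min replicate 2 (180 higher, 412 lower), and 54 and 53 without those at 240 min. Of the calls without the 120 min replicates 70.4% and 65.6% were higher. From 180 to 240 min it was 16 without 0 min replicate 2, 13 without either 120 min array, 0 without 180 min replicate 1 or either 240 min array, and 341 without 180 min replicate 2. The counts of 0 had 1049, 1233 and 922 probe sets at an unadjusted p under 0.05. Scaling to the median moved the share of higher calls from 49.4% to 35.2% between 120 and 180 min and from 55.6% to 90.3% between 180 and 240 min, where it moved the median of all probe sets from -0.021 to 0.12.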

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

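Genes named for their largest rises or falls, or followed at every time, appear here where limma's test of the difference between neighbouring times passed. Of the tests in this part, those of FOS under other offsets, of 180 min arrays as 30 min samples and of degraded RNA, and the change from 120 to 180 min of the genes raised at 30 min under other settings, were chosen after the result was seen.

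From 30 to 120 min 5 such genes rose. TMEM158 rose by 1.27 ± 0.18 (adjusted p = 0.0034), CLDN4 by 1.24 ± 0.16 (adjusted p = 0.0017) and FZD7 by 1.06 ± 0.16 (adjusted p = 0.0054). FOSL1 rose by 0.91 ± 0.18 (adjusted p = 0.031) and MAFF by 0.59 ± 0.11 (adjusted p = 0.023). Early genes fell, FOS by -5.55 ± 0.19 (adjusted p = 4.8e-09; -7.11 with no offset and -4.29 with the larger one), EGR1 by -2.72 ± 0.15 (adjusted p = 1.3e-06), DUSP1 by -2.23 ± 0.15 (adjusted p = 6.2e-06) and ATF3 by -1.55 ± 0.11 (adjusted p = 1.8e-05). FOSB fell by -1.48 ± 0.16 (adjusted p = 0.00051), EGR3 by -1.39 ± 0.18 (adjusted p = 0.0017), NR4A2 by -0.99 ± 0.19 (adjusted p = 0.025) and NR4A1 by -0.94 ± 0.17 (adjusted p = 0.017). The phosphatase genes DUSP6 and DUSP5 fell by -1.97 ± 0.25 (adjusted p = 0.0014) and -1.03 ± 0.11 (adjusted p = 0.00045). DDIT4 fell by -1.22 ± 0.11 (adjusted p = 0.00012), BCL6 by -1.07 ± 0.16 (adjusted p = 0.0043), FZD5 by -0.97 ± 0.17 (adjusted p = 0.012) and TXNIP by -0.78 ± 0.15 (adjusted p = 0.023). PTGS2 fell by -0.77 ± 0.15 (adjusted p = 0.025), NCK1 by -0.72 ± 0.15 (adjusted p = 0.042) and PIK3IP1 by -0.70 ± 0.12 (adjusted p = 0.013).

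Some of these differences had an adjusted p of 0.05 or more without single arrays (ranges are over the arrays left out). TMEM158 did so without 120 min replicate 1 (0.056; range 0.0042 to 0.056) and BCL6 without 120 min replicate 2 (0.087; range 0.005 to 0.087). FZD7 did so without 30 min replicate 2 (0.061) or either array of 120 min (0.052 and 0.087; range 0.0048 to 0.087). FOSL1 did so without either array of 30 min (0.21 and 0.062), 120 min (0.18 and 0.23) or 240 min (0.054 and 0.054; range 0.0046 to 0.23). MAFF did so without either array of 30 min (0.058 and 0.15) or 120 min (0.18 and 0.17; range 0.017 to 0.18), and TXNIP without the same arrays (0.12, 0.11, 0.17 and 0.18; range 0.011 to 0.18). PIK3IP1 did so without 30 min replicate 1 (0.097) or 120 min replicate 2 (0.17; range 0.013 to 0.17). NCK1 did so without either array of 0 min (0.064 and 0.063), 30 min (0.12 and 0.22) or 120 min (0.39 and 0.079; range 0.038 to 0.39). PTGS2 did so without either array of 30 min (0.15 and 0.093), 120 min (0.17 and 0.2) or 240 min (0.053 and 0.054; range 0.022 to 0.2). NR4A1 did so without 30 min replicate 2 (0.15) or either array of 120 min (0.14 and 0.14; range 0.0082 to 0.15), and FZD5 without the same arrays (0.11, 0.12 and 0.1; range 0.0089 to 0.12). NR4A2 did so without 30 min replicate 1 (0.19) or either array of 120 min (0.13 and 0.22; range 0.013 to 0.22).

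From 120 to 180 min FOS rose by 3.57 ± 0.19 (adjusted p = 1.3e-06; 5.07 with no offset and 2.42 with the larger one), EGR1 by 2.20 ± 0.15, CYP1B1 by 1.80 ± 0.12 and ATF3 by 1.69 ± 0.11 (adjusted p = 9.1e-06 for each of the last 3). EGR3 rose by 1.56 ± 0.18 (adjusted p = 0.001), MT1E by 1.46 ± 0.13 (adjusted p = 6.8e-05), FOSB by 1.39 ± 0.16 (adjusted p = 0.001) and DUSP1 by 1.23 ± 0.15 (adjusted p = 0.0012). NR4A2 rose by 1.14 ± 0.19 (adjusted p = 0.019), NR4A1 by 1.02 ± 0.17 (adjusted p = 0.017), PTGS2 by 0.81 ± 0.15 (adjusted p = 0.029) and DUSP5 by 0.72 ± 0.11 (adjusted p = 0.0094). IL1RL1 fell by -1.96 ± 0.39 (adjusted p = 0.045), ALOX12P2 by -1.68 ± 0.29 (adjusted p = 0.019), ANGPTL4 by -1.15 ± 0.14 (adjusted p = 0.0016) and TRIB2 by -0.90 ± 0.14 (adjusted p = 0.011). NR4A2 was past 0.05 without either array of 120 min (0.12 and 0.16) or 180 min replicate 1 (0.066; range 0.007 to 0.16), NR4A1 without the same arrays (0.16, 0.12 and 0.11; range 0.0058 to 0.16) and DUSP5 too (0.13, 0.084 and 0.086; range 0.012 to 0.13). PTGS2 was so without either array of 120 min (0.2 and 0.19), 180 min replicate 1 (0.2) or either array of 240 min (0.068 and 0.067; range 0.02 to 0.2), and ALOX12P2 without the same arrays (0.19, 0.19, 0.075, 0.055 and 0.053; range 0.017 to 0.19). TRIB2 was so without 120 min replicate 1 (0.17) or 180 min replicate 1 (0.11; range 0.011 to 0.17). IL1RL1 was so without either array of 0 min (0.058 and 0.061), 30 min (0.058 and 0.058), 120 min (0.39 and 0.22) or 240 min (0.077 and 0.074) or 180 min replicate 1 (0.24; range 0.0049 to 0.39).

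From 180 to 240 min TMEM158 rose by 1.23 ± 0.18 (adjusted p = 0.015), RAB5C by 1.07 ± 0.18 (adjusted p = 0.03) and MT1E by 0.96 ± 0.13 (adjusted p = 0.0099). COQ8A fell by -1.83 ± 0.33 (adjusted p = 0.041) and HELLS by -1.05 ± 0.18 (adjusted p = 0.031). Each of the 5 was past 0.05 without 180 min replicate 1 or either array of 240 min, TMEM158 with 0.15, 0.16 and 0.16 (range 0.014 to 0.16) and MT1E with 0.058, 0.1 and 0.15 (range 0.006 to 0.15). RAB5C had 0.14, 0.12 and 0.31, and 0.052 without either array of 120 min (range 0.018 to 0.31). HELLS had 0.17, 0.17 and 0.29, with 0.065 and 0.062 without the arrays of 0 min and 0.07 and 0.073 without those of 120 min (range 0.029 to 0.29). COQ8A had 0.17, 0.3 and 0.21, with 0.057 without 0 min replicate 2, 0.063 without either array of 30 min and 0.077 and 0.079 without those of 120 min (range 0.049 to 0.3).

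The 51 genes raised at 30 min had a median change of 0.35 from 120 to 180 min, with 39 of them higher, 15 called higher and 0 called lower by limma (8 called higher without 180 min replicate 1 or 120 min replicate 1, 9 without 120 min replicate 2). Called lower were 2 without 180 min replicate 2 and 1 with quantile normalisation. The tables argue against 180 min replicate 1 as the cause, since the median was 0.37 with 40 higher without it (0.28 to 0.37 over the arrays left out). They argue against 240 min arrays being 30 min samples, with 288 probe sets apart, and against the 180 min arrays being such, with 14 apart without replicate 1. Disturbance of the cells near harvest or a change of medium cannot be told apart from an effect of low pH, because the design held 0 arrays of untreated cells beyond 0 min, so both stay open.

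Replicate 1 at 180 min stood apart from the other 9 arrays, with r = 0.944 to its mate against 0.9665 to 0.9756 in the other pairs. An intensity-dependent difference in signal is argued against, since r was 0.945 after quantile normalisation against 0.966 to 0.975 in the other pairs. Degraded RNA is argued against too, since the 3' minus 5' log2 difference was -0.17 for GAPDH (-0.32 to -0.14 on the others) and -0.1 for ACTB (-0.11 to 0.21). Another state of the culture or a step of the hybridisation stays open, and no biological explanation was tested.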

How the results depend on the processing

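Counts of probe sets moved by more than 1.5 times under some settings. Of 234 named gene calls 0 reversed, which for most settings was fixed in advance. Each call had both low pH arrays beyond both 0 min arrays, so leaving out 1 array could not change its sign. Without the trend or the filter, or with the replicate block, the log2 change itself stayed the same. Without the intensity trend the counts were 39, 142, 107 and 249 at 30, 120, 180 and 240 min against 0 min (from 76, 263, 177 and 441), 52 from 30 to 120 min (from 169), 26 from 120 to 180 min (from 87), 0 from 180 to 240 min (from 36, with 1482 at an unadjusted p under 0.05) and 201 over the time course (from 442). At 240 min 81.5% of the calls without the trend were higher, against 70.7%. With 1 probe set per gene the counts were 169 at 120 min and 55 from 120 to 180 min, which follows from fewer probe sets. With only the groups compared in the fit, which leaves fewer arrays, they were 112 at 180 min, 27 from 120 to 180 min and 18 from 180 to 240 min. With no filter on dim probe sets 15 were called from 180 to 240 min, and the cause was not tested. Camera with an estimated correlation put 31 of 57 list calls past the threshold. Quantile normalisation, median scaling and both other offsets moved 0 of these counts by as much. Named gene calls were lost for 63 of 234 without the trend, 30 with no filter, 26 with only the groups compared, 23 with median scaling, 15 with the replicate block and 7 with quantile normalisation. Leaving out 1 array lost 54 and 69 without the 0 min replicates 1 and 2, 39 and 38 without those at 240 min, 34 and 33 without those at 120 min, and 7 to 12 without those at 30 or 180 min. HES1, TNFAIP2, SLC7A5, CYP1A1 and TIPARP, not among the 234, were run under the same alternatives after their results were seen.

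Leave-one-out counts, where the lone array left in a group is assumed to vary like the others, ran from 52 to 81 at 30 min, 118 (without 120 min replicate 1) to 322 (without 180 min replicate 1) at 120 min, 101 (without 0 min replicate 2) to 490 (without 180 min replicate 2) at 180 min, and 219 (without 240 min replicate 2) to 518 (without 180 min replicate 1) at 240 min. They ran from 47 (without 120 min replicate 2) to 208 (without 180 min replicate 1) from 30 to 120 min and 27 (without 120 min replicate 1) to 592 (without 180 min replicate 2) from 120 to 180 min. From 180 to 240 min they ran from 0 (without 180 min replicate 1, with 1049 at an unadjusted p under 0.05, or either array of 240 min, with 1233 and 922) to 341 (without 180 min replicate 2). For probe sets changed over the time course they ran from 267 (without 240 min replicate 1) to 811 (without 180 min replicate 2), and list calls from 50 to 58. In the comparisons that include 180 min and over the time course, counts were highest where 180 min replicate 1 was left as the lone array of its group, and the cause was not tested.

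With the replicate block the counts were 71, 234, 167 and 372 against 0 min, 144, 65 and 13 between neighbouring times, 373 for probe sets changed over the time course, and 58 list calls. The replicate numbers do not pair samples, since deviations from the group means correlated between groups at -0.11 to 0.09, with 0 of the pairs of groups over 0.1. A batch alternative was not run, because the fields for lot and scan in the experiment sheets are empty. All signals were taken as deposited, with any background step before that left as it was.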

Other observations

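In this part the list of aryl hydrocarbon receptor targets was chosen after CYP1A1, CYP1B1 and TIPARP had been seen, and the test without 180 min replicate 1 and the other reruns of these genes were chosen after the results were seen.

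CYP1A1, CYP1B1 and TIPARP, targets of the aryl hydrocarbon receptor, rose late, although TIPARP also passed at 30 min (0.55 ± 0.11, adjusted p = 0.044, and 0.052 to 0.4 without any 1 of the 10 arrays; range over alternatives 0.02 to 0.4) and at 120 min (0.67 ± 0.11, adjusted p = 0.0053, and 0.081 and 0.075 without 0 min replicate 2 and 120 min replicate 1; range 0.0024 to 0.081). CYP1B1 rose by 2.19 ± 0.12 at 180 min and 2.58 ± 0.12 at 240 min, CYP1A1 by 1.86 ± 0.25 (adjusted p = 0.001) and 2.02 ± 0.25 (adjusted p = 0.00029), and TIPARP by 1.43 ± 0.11 and 1.56 ± 0.11 (adjusted p = 1.6e-06 at 240 min), n = 2 arrays per group. The tables argue against 180 min replicate 1 as the cause at 180 min, since 3 of the 3 genes kept their call without it (CYP1B1 2.14, CYP1A1 1.82 with adjusted p = 0.011, TIPARP 1.40). Whether other targets of the aryl hydrocarbon receptor rose with them stays open, since 1 of 5 other measured members passed at 240 min, SLC7A5 at 0.47 ± 0.12 (adjusted p = 0.046, lost without 0 min replicate 2 or any 1 of the 30, 120 or 240 min arrays, range over alternatives 0.01 to 0.38), while NQO1 had -0.06. Activity of this receptor may explain the 3 rises, as a hypothesis found and tested on the same data.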
